A study of Homo sapiens with 14 samples.

How the data were processed

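Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in MOLM-13 cells, a human acute myeloid leukemia line that carries an MLL (KMT2A) fusion gene. Per the labels' protocols, the cells were transduced for 4 days with a lentiviral CRISPR-Cas9 construct, either the control construct labelled EV or one with a guide RNA against KAT6A (sgKAT6A). The antibody labels name 3 lysine acetylation marks, K9ac, K14ac and K23ac, without naming the histone. Of the 14 samples, 12 are immunoprecipitations (2 arms, 3 marks and 2 samples per arm and mark) and 2 are inputs. The inputs were not used here, so no enrichment over input was computed. The columns of values carry the arm, the mark and a letter, which names no replicate number of the labels. Libraries are therefore called library a and library b within an arm.

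For each mark the authors deposited a table of genomic regions with CPM values for the 4 libraries, with 64088 regions for K9ac, 43978 for K14ac and 14053 for K23ac. Although the tables are titled as TPM, the values sum to 1000000 in each library. The low values of a library are whole multiples of the same step whatever the region's length, so the deposited unit is CPM, reads per 1000000 reads counted in the table's own regions. Dividing by that step gave whole reads for 100% of the low values tested, within 0.1 read. Bowtie2, SAMtools, MACS2 and bedtools and the build hg38 are named in the submitters' processing notes. Their roles, versions and settings, the treatment of duplicate reads, and whether regions were called on pooled samples are not given in the sources used here. Because CPM is relative to the reads inside the regions, a change of the same size in all regions leaves no trace, and more background in a library raises weak regions and lowers strong ones. The tables were normalized separately, so no test was made between marks.

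The recovered reads in regions set the precision. For K9ac they numbered 58049013 and 98860472 in EV libraries a and b and 16798715 and 80586070 in sgKAT6A libraries a and b. For K14ac the 4 totals in the same order were 7161678, 1908687, 4391078 and 4228704. For K23ac they were 1486876, 775683, 655005 and 1933809. The median region held 31 to 105 reads per library for K9ac, 21 to 48 for K14ac and 31 to 91 for K23ac. Libraries of the same arm and mark differed by more than sampling noise, with a chi-square per degree of freedom of 3.31 to 9.44, so none was counted as a duplicate.

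Regions were placed on the human RefSeq gene table of GRCh38, the assembly that hg38 denotes, with 20033 protein-coding genes. That table gives no strand, so a region within 1000 bp of either end of a protein-coding gene was called a gene-end region in place of a promoter region. The gene-end share was 21.5% of regions for K9ac, 34.1% for K14ac and 65.5% for K23ac, and 8.6%, 6.8% and 7.8% after all regions were shifted by 50000 bp. A gene was represented by the gene-end region with the highest mean CPM.

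Within each mark, the 2 sgKAT6A libraries were compared with the 2 EV libraries by limma's moderated test with a variance trend, two-sided, on log2(CPM + 1), without a replicate block. Regions with a CPM of at least 1 in at least 2 of the 4 libraries were tested. Fold changes are on the log2(CPM + 1) scale, which understates the change of weak regions. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 is called a change. The labels do not say that samples of an arm came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The test had been planned for TPM values and was kept for CPM.

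There were 17 gene lists: the MLL fusion and HOX program, myeloid differentiation, KAT6 complexes and KAT7, YEATS readers and the elongation complex, other histone acetyltransferases and deacetylases, housekeeping genes, cytosolic ribosomal proteins, cell cycle and DNA replication, MYC targets and nucleolar biogenesis, p53 response, interferon response, NF-kB and early response, cell cycle inhibitors, histone genes, and markers of erythroid and megakaryocytic cells, of lymphoid cells and of non-blood tissues. Of their 536 genes 535 matched the gene table. Each list with at least 5 measured genes was tested with camera (limma) at a preset correlation of 0.01 against the other genes, with adjustment over the lists of a mark. A region shared by several genes entered once per gene. Such a region is often named below by its listed gene alone, as BST2 with MVB12A or TNF with LTA. Its change cannot be assigned to a single gene. Camera with an estimated correlation and fry were run beside it, and member genes were also adjusted over the list alone. List medians were set against 10000 random lists of the same size matched on mean CPM in 20 strength classes.

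The lists, the tests, the settings named as chosen in advance and the rule for named genes were chosen before the data were examined. For each mark the rule takes the 10 largest falls and the 10 largest rises among changed regions with a mean CPM at or above the table's median and with both sgKAT6A libraries on the same side of both EV libraries. It also takes 20 genes whatever their result and up to 4 members of each list with the smallest p. Where fewer than 5 regions passed, it takes the 5 largest falls and rises by moderated t instead. Some genes that the rule takes are not reported here.

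The settings chosen in advance were pseudocounts of 0.1 and 5, no filter, regions at or above the median mean CPM, median-centred, quantile and cyclic loess scaling, no variance trend, a robust trend, an adjusted p of 0.1, a minimum fold of 1.5, a gene-end window of 2500 bp, a reciprocal overlap of 50% and each library left out in turn. A block by replicate number had been chosen in advance too, but the columns carry no such number, and the column letter was used in its place. Chosen after seeing the data were that block by letter, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, each shared region counted once, regions inside genes, loess scaling without sgKAT6A library a, and loess scaling for the comparisons of gene ends with other regions and between marks. The limma test was tested on simulated data with 100 regions changed 1.5-fold and 100 changed 2-fold at each mark's read totals and spread. It recovered 72% and 84% of them for K9ac among 36882 regions, 0% and 14% for K14ac among 43940, and 11% and 48% for K23ac among 14053. The changed regions were drawn from the stronger tested regions, those with a mean CPM at or above the median. No shift of a whole library was simulated, and recovery at weaker regions was not measured. No genome sequence was used, so GC content was not checked.

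The analysis used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, GenomicRanges 1.54.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.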

Results

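The series asks how targeting KAT6A, a histone acetyltransferase of the MYST family, changes the chromatin of acute myeloid leukemia cells. Acetylation marks K9ac, K14ac and K23ac were profiled by ChIP-seq in MOLM-13 cells after 4 days of transduction, with 2 EV and 2 sgKAT6A libraries per mark. Reads in regions ranged from 16798715 to 98860472 per library for K9ac, from 1908687 to 7161678 for K14ac and from 655005 to 1933809 for K23ac. Values are given as CPM with the SD over 2 libraries, and changes as log2 fold change of sgKAT6A over EV with its standard error (SE) and the Benjamini-Hochberg adjusted p of limma.

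At KAT6A itself, acetylation did not differ between the arms beyond the spread of the libraries in any mark. The K9ac region at the KAT6A gene end (hg38 chromosome 8, 42049914 to 42053093) held 247 and 214 CPM in EV libraries a and b, and 197.3 and 226 CPM in sgKAT6A libraries a and b (log2 fold change −0.12, SE 0.073, limma adjusted p = 0.327). The stronger K14ac region there (42050430 to 42052137) had a log2 fold change of 0.36 (SE 0.28, limma adjusted p = 0.837) and the K23ac region (42051036 to 42051992) of 0.27 (SE 0.209, limma adjusted p = 0.979). Acetylation at this gene end does not measure loss of the KAT6A protein. Single libraries moved these tests: K9ac passed without sgKAT6A library b (−0.22, limma adjusted p = 3.03e-07, over all alternatives up to 0.998), and K14ac passed without EV library a (0.64, limma adjusted p = 0.000896, over all alternatives up to 1). The K23ac change, which passed in no setting, was 0.637 without EV library a and −0.104 without EV library b.

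K9ac fell at the receptor tyrosine kinase gene FLT3, at the leukemia transcription factor gene MEIS1 and at PHGDH, which encodes the first enzyme of serine synthesis. It rose at genes of mature phagocytes such as CYBB, the catalytic subunit of the phagocyte NADPH oxidase, and LYZ, lysozyme. Of 36882 regions tested, 983 rose and 366 fell with sgKAT6A by limma, 72.9% of the changed regions being higher. The arms did not overlap in 56.9% of tested regions, against 33.3% by chance for a single region. All regions share the same libraries, so a shift of a whole library separates the arms in many regions at once. The excess over 33.3% therefore does not measure change region by region. The regions that fell were strong and changed little (median 117.7 CPM, median log2 fold change −0.31), and those that rose were weaker and changed more (median 17.7 CPM, median 0.59). The split depends on scaling, with 44.7% of changes higher after median-centring, 58.3% after quantile and 58.8% after loess scaling. The median change of all tested regions moved from 0.17 to −0.111, −0.005 and −0.006 in the same order. The count was 269 without EV library a, 335 without EV library b, 5242 without sgKAT6A library a and 19630 without sgKAT6A library b. It was 1840 with edgeR, 441 with DESeq2 (49% higher) and 0 in limma without a variance trend, where 6988 regions had an unadjusted p under 0.05.

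The largest K9ac falls included ADM2, a peptide hormone of the adrenomedullin family, from 14.9 ± 1.49 to 7.42 ± 0.204 CPM (SD, n = 2), with a log2 fold change of −0.92 (SE 0.14, limma adjusted p = 0.00211). K9ac fell at MTSS2, an actin-binding membrane protein, by 0.85 (SE 0.0777) on the log2 scale, and at PHGDH from 48.5 ± 0.326 to 27.6 ± 2.77 CPM, a log2 fold change of −0.80 (SE 0.0836, limma adjusted p = 1.02e-04). The region at LAMP5, a lysosome-associated membrane protein, spans 9503169 to 9521815 on chromosome 20 and fell from 874 ± 8.72 to 511 ± 10.7 CPM (SD, n = 2). At FLT3 (chromosome 13, 28098274 to 28102790) K9ac fell from 330 ± 21.6 to 207 ± 2.49 CPM, a log2 fold change of −0.66 (SE 0.0556, limma adjusted p = 2.57e-05). Regions inside RSRC1 and the SUMO protease gene SENP6 were also among the 10 largest falls. SHISA2, the annexin receptor gene ANXA2R and the ubiquitin ligase gene RNF220 make up the rest, all between −0.89 and −0.63.

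The largest K9ac rises included genes that neutrophils and monocytes express. CYBB (chromosome X, 37779696 to 37781707) rose from 3.10 ± 0.3 to 15.3 ± 4.9 CPM, a log2 fold change of 1.97 (SE 0.206, limma adjusted p = 1.02e-04). FCAR, the Fc receptor for IgA (chromosome 19, 54873939 to 54876255), rose from 6.02 ± 1.28 to 23.8 ± 2.83 CPM, a log2 fold change of 1.83 (SE 0.149, limma adjusted p = 2.38e-05). K9ac also rose at S100A8, a calcium-binding protein of neutrophils and monocytes (1.37, SE 0.227), at SERPINB2, a plasminogen activator inhibitor of monocytes (1.27, SE 0.272), and inside PTAFR, the receptor for platelet-activating factor (1.25, SE 0.142). SEMA6B and regions inside ARHGEF10L, ASB2, DNAJC3 and the IgE receptor gene FCER2 complete the 10 largest rises, between 1.19 and 1.64. Of the 29 named changed genes 15 passed without EV library a, 18 without EV library b and 0 without a variance trend. Leaving out sgKAT6A library a or b kept the call of all 1349 changed regions, since the spread then comes from the EV libraries alone, so it does not set these genes apart.

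**Figure D1:**
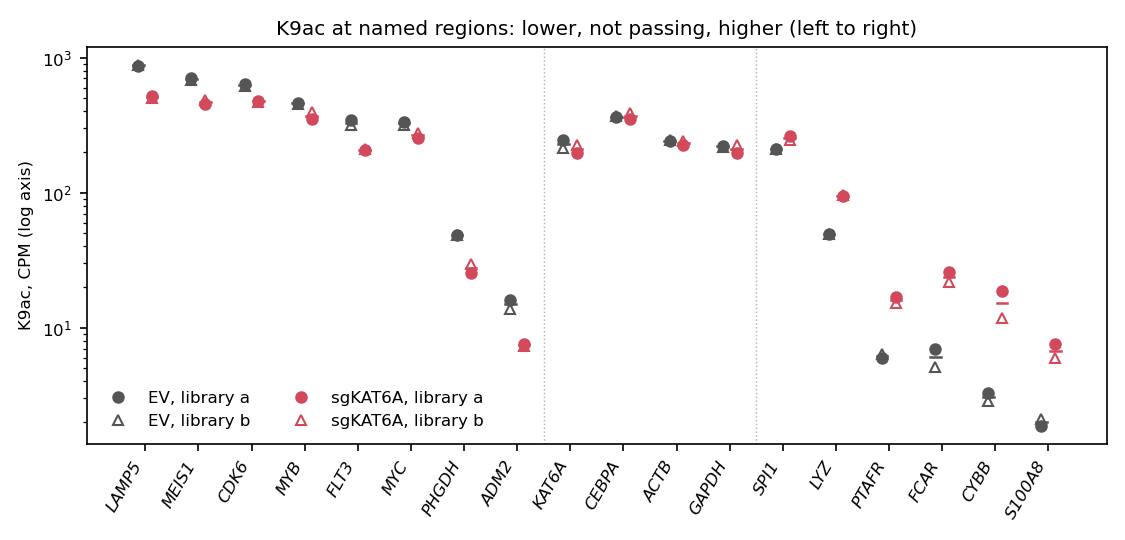
K9ac in CPM on a log axis at 18 named regions, with each EV library in grey, each sgKAT6A library in red and short bars for the mean of 2 libraries. FCAR, CYBB and S100A8 lie higher in both sgKAT6A libraries and LAMP5, FLT3 and MEIS1 lower, while SPI1, drawn among the higher regions, has a log2 change of −0.005 after median-centring, and ACTB and GAPDH change sign under quantile and loess scaling. With quantile and loess scaling SPI1 has 0.365 and 0.398, and CEBPA, drawn among those not passing, passes as higher (0.133 and 0.176).

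K9ac fell across the MLL fusion and HOX program, the genes kept active by MLL fusion proteins in leukemia. Of 30 measured genes 19 fell, 0 rose and 11 did not pass, with 23 lower and 0 higher adjusted over the list alone. The 30 genes share 26 regions and the 19 share 15. The list lay lower than other genes (median −0.26, limma camera adjusted p = 3.19e-13). With an estimated correlation the adjusted p = 0.328, and by fry the adjusted p = 0.0702. After LAMP5 and FLT3 the members with the smallest p were MEIS1, a cofactor of HOX proteins (690 ± 17.1 to 471 ± 23 CPM, log2 fold change −0.55, SE 0.0519, limma adjusted p = 5.18e-05), and SKIDA1 (−0.47, SE 0.0499). The cell cycle kinase gene CDK6 fell by 0.40 on the log2 scale, and the proto-oncogenes MYB and MYC by 0.30 and 0.29. A single region across the HOXA cluster, which covers HOXA9 and HOXA10, fell by 0.27 (limma adjusted p = 0.0106), and the survival gene BCL2 by 0.24 (limma adjusted p = 0.026), whereas the HOX cofactor gene PBX3 did not pass (−0.15, limma adjusted p = 0.103). After median-centring the falls were larger in size but LAMP5 (−1.05), FLT3 (−0.942), MEIS1 (−0.827), CDK6 (−0.679), MYB (−0.578), MYC (−0.567), the HOXA9 and HOXA10 region (−0.546) and BCL2 (−0.52) did not pass. Loess scaling left 10 members lower with a median of −0.05, and neither BCL2 (−0.132) nor the HOXA9 and HOXA10 region (−0.047, and −0.018 with quantile scaling) passed.

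K9ac rose at genes of myeloid differentiation. Of 44 measured genes 11 rose, 0 fell and 33 did not pass, with 19 higher and 2 lower adjusted over the list alone. The list lay higher than other genes (median 0.27, limma camera adjusted p = 4.51e-10; adjusted p = 0.277 with an estimated correlation). LYZ rose from 49.6 ± 0.205 to 95.1 ± 1.38 CPM (log2 fold change 0.93, SE 0.0622, limma adjusted p = 2.59e-06), the interferon-inducible nuclear protein gene MNDA rose by 0.82 (SE 0.0773) and ANXA1, an annexin of phagocytes, by 1.10 (SE 0.115). The myeloid master regulator SPI1 rose by 0.27 (limma adjusted p = 0.0104), with a sign change after median-centring (−0.005). With quantile and loess scaling SPI1 rose by 0.365 and 0.398. The regulator CEBPA (0.01, limma adjusted p = 0.904), the monocyte receptor CD14 (0.46, limma adjusted p = 0.229), the integrin ITGAM (0.86, limma adjusted p = 0.0656) and myeloperoxidase, MPO (0.43, limma adjusted p = 0.0858), did not pass. CEBPA passed as higher with quantile (0.133) and loess scaling (0.176, limma adjusted p = 0.00509), but was −0.265 after median-centring. ITGAM passed after median-centring (0.579, limma adjusted p = 0.0342) but not with quantile or loess scaling. CD14 and MPO passed under none of these scalings. The list lay at percentile 100 of random lists of the same strength, whose median was 0.025. After median-centring its median was −0.006 while camera still placed it above other genes, and LYZ (0.649) did not pass. With quantile and loess scaling the list's median was 0.167 and 0.177.

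Another 3 lists lay higher than other genes by camera at the preset correlation, with 1 to 5 members that passed. In the NF-kB and early response list 5 of 21 genes rose, 0 fell and 16 did not pass (7 higher and 1 lower adjusted over the list alone), among them the chemokine CXCL8 (0.97, SE 0.0922), the adhesion molecule ICAM1 (0.67, SE 0.0742), IER3 and TNF. The median was 0.11 (limma camera adjusted p = 0.000426; adjusted p = 0.328 with an estimated correlation) and −0.169 after median-centring. With quantile and loess scaling it was 0.161 and 0.158. Of 27 interferon response genes 1 passed, BST2, which tethers virus particles to the cell (0.57, SE 0.0739), with 11 higher and 0 lower adjusted over the list alone. The BST2 region also lies at an end of MVB12A. The interferon list's median was 0.26 (limma camera adjusted p = 3.7e-08; adjusted p = 0.328 with an estimated correlation) and −0.016 after median-centring. With quantile and loess scaling it was 0.157 and 0.142. Of 6 erythroid and megakaryocytic marker genes 1 rose, also adjusted over the list alone: NFE2, a factor of megakaryocyte and erythroid genes that granulocytic cells also express (0.49). That list's median of 0.38 (limma camera adjusted p = 0.00776; adjusted p = 0.328 with an estimated correlation) lay at percentile 94.7 of random lists of the same strength, whose median was 0.189. It did not pass under quantile or loess scaling or without sgKAT6A library a (median 0.225).

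K9ac fell at members of 4 lists of proliferation and of abundant gene products. Among histone genes 31 of 47 fell, 0 rose and 16 did not pass (44 lower and 0 higher adjusted over the list alone). The 31 share 16 regions, such as one over H2AC13, H2BC13 and H3C10 (−0.41, SE 0.0527) and one at H1-4 (−0.36, SE 0.0527). The histone median was −0.31 (limma camera adjusted p = 1.68e-27, and 0.277 with an estimated correlation). The 47 genes share 29 regions, and a shared region counted once per gene, which makes the p at the preset correlation too small. In the cell cycle and DNA replication list 8 of 39 fell and 0 rose (20 lower and 0 higher over the list alone), including the helicase genes MCM6 (−0.34, SE 0.0625) and MCM4 (−0.31) and the licensing factors CDT1 (−0.27) and CDC6 (−0.31). The median was −0.16 (limma camera adjusted p = 1.34e-09; adjusted p = 0.415 with an estimated correlation). Of 30 MYC targets 5 fell and 0 rose (20 lower and 1 higher adjusted over the list alone), among them the chaperonin genes HSPD1 and HSPE1, which share a region (−0.26), EIF4E (−0.25) and NOLC1 (−0.32). Their list had a median of −0.17 (limma camera adjusted p = 1.18e-07; adjusted p = 0.406 with an estimated correlation). Of 74 ribosomal protein genes 5 fell and 0 rose (9 lower and 0 higher adjusted over the list alone), among them RPL3, RPL34 and RPL14. The ribosomal median was −0.115 (limma camera adjusted p = 4.51e-10; adjusted p = 0.412 with an estimated correlation). These 4 lists lay at percentiles 0 to 0.01 of random lists of the same strength, and their medians stayed negative under quantile and loess scaling, as did that of the housekeeping list (−0.024 and −0.013). Under median-centred scaling they stayed negative by construction, since it lowered every log2 change by the same amount. The housekeeping list did not stand apart from genes of its strength, at percentile 38.8 of random lists with a median of −0.062. Among its 24 genes TFRC, the transferrin receptor, fell (−0.22) and 0 rose (1 lower and 0 higher adjusted over the list alone). The median of −0.07 (limma camera adjusted p = 0.0323; adjusted p = 0.517 with an estimated correlation) did not pass under any of these scalings. ACTB (−0.06) and GAPDH (−0.07) did not pass and changed sign under quantile and loess scaling.

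The 7 remaining lists did not pass for K9ac. In KAT6 complexes and KAT7 the subunit gene JADE1 fell (−0.20) among 12 genes, with 4 lower adjusted over the list alone (median −0.08, limma camera adjusted p = 0.0521). Among 25 YEATS reader and elongation genes the elongation factor gene ELL2 rose (0.50), with 1 higher and 2 lower adjusted over the list alone (median −0.07, limma camera adjusted p = 0.101). Of 18 other acetyltransferase and deacetylase genes 0 changed by limma over all regions and 1 rose and 1 fell adjusted over the list alone (median −0.06, limma camera adjusted p = 0.217; 0.007 and 0.011 under quantile and loess scaling). Among 10 cell cycle inhibitors CDKN1B (−0.30) and CDKN2C (−0.21) fell, with 3 lower adjusted over the list alone (limma camera adjusted p = 0.0966), and CDKN1A did not pass (0.12, limma adjusted p = 0.31). Without sgKAT6A library a this list passed as lower. Of 23 p53 response genes BTG2, an antiproliferative factor, rose (0.27), with 2 higher adjusted over the list alone. The median was 0.04 (limma camera adjusted p = 0.127) and −0.237 after median-centring, and the list passed as higher under quantile and loess scaling. Of 9 lymphoid markers the cytotoxic granule gene NKG7 rose (0.42), also adjusted over the list alone (limma camera adjusted p = 0.213), and of 6 markers of non-blood tissues 0 passed on either basis (limma camera adjusted p = 0.509). Medians of both lists were negative under median-centred, quantile and loess scaling. By limma's fry, which asks whether the genes of a list move on balance one way, 3 of the 17 lists passed: myeloid differentiation, NF-kB and early response, and histone genes (adjusted p = 0.0347 for each). The other 7 lists that camera called did not pass by fry, with an adjusted p of 0.0635 for interferon response, 0.0702 for the MLL fusion and HOX program, 0.0822 for erythroid and megakaryocytic markers, 0.0939 for ribosomal proteins, 0.132 for MYC targets, 0.136 for cell cycle and 0.285 for housekeeping genes.

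**Figure D2:**
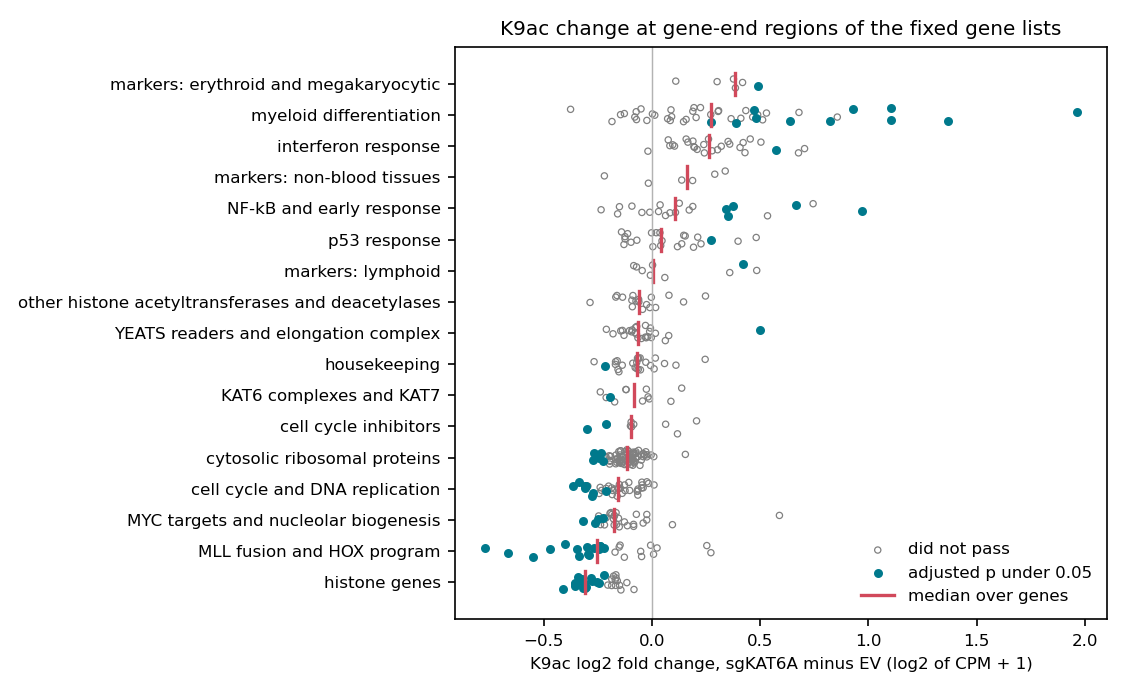
K9ac log2 fold change of sgKAT6A over EV (log2 of CPM + 1, horizontal axis) at gene-end regions of the 17 gene lists, each point a region, filled where the limma adjusted p is under 0.05, with the list's median over genes in red. Histone genes and the MLL fusion and HOX program lie lowest at −0.31 and −0.26, while the positive medians of myeloid differentiation, interferon response and NF-kB genes turn to −0.006, −0.016 and −0.169 after median-centring, and those of p53 response, lymphoid and non-blood lists turn negative too. Medians of the myeloid, interferon and NF-kB lists stay positive with quantile (0.167, 0.157 and 0.161) and loess scaling (0.177, 0.142 and 0.158).

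K9ac changes differed with the place and strength of the region. Among 11820 gene-end regions 340 rose and 286 fell, among 15026 regions inside genes 385 rose and 53 fell, and among 10036 regions outside genes 258 rose and 27 fell. The median log2 change of gene-end regions was 0.229 below that of the others, a difference of −0.393 in sgKAT6A library a and −0.081 in library b, and of −0.009 with loess scaling, a setting chosen after seeing the data for this comparison. When the regions were split into 10 classes by strength, sgKAT6A library a stood 0.48 above the EV mean and library b 0.12 in the class with a median of 2.45 CPM. In the strongest class they stood at −0.11 and −0.04. Library a also had the fewest K9ac reads and the lowest share of reads in the strongest 1% of regions, 17.7% against 18.6% in sgKAT6A library b and 20% and 19.6% in EV libraries a and b.

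**Figure D3:**
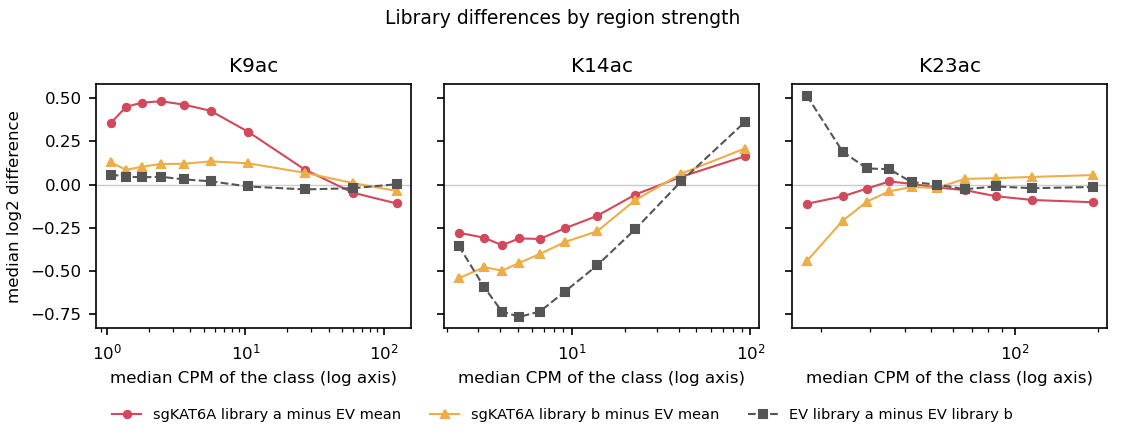
Median log2 difference (vertical axis) over 10 classes of regions ordered by CPM (log axis) for each sgKAT6A library against the EV mean and for EV library a against EV library b, in each mark. For K9ac sgKAT6A library a rises by up to 0.48 at weak regions, while the EV libraries of K14ac differ by up to 0.76 in size.

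For K14ac 0 of 43940 regions passed by limma, with 2951 at an unadjusted p under 0.05, a smallest adjusted p of 0.266, and 0 by edgeR and by DESeq2. The largest falls by moderated t, none of which passed, were at AMPD3, an AMP deaminase (33.2 ± 4.24 to 9.52 ± 0.254 CPM, log2 fold change −1.69, SE 0.335), and inside PICK1, KCNQ3, CPQ and SENP6. The K14ac region inside SENP6 had a log2 fold change of −1.41 (limma adjusted p = 0.442). KCNQ3 and CPQ lie on chromosome 8, where the median K14ac change was −0.381, against −0.169 over all tested regions. On that chromosome EV library b stood 0.478 above EV library a with loess scaling. Part of these falls may belong to a shift of the whole chromosome, which was not tested. The largest rises, which did not pass either, included SFXN5, a mitochondrial carrier (1.11, SE 0.286), DNTTIP1, SMARCB1 and SKIL (0.82, SE 0.257). Neither MEIS1 (−0.36, SE 0.28), FLT3 (−0.26, SE 0.314) nor LYZ (0.45, SE 0.269) passed. Of the 14 lists tested 0 passed by limma camera (smallest adjusted p = 0.161, ribosomal proteins; adjusted p = 0.928 with an estimated correlation) and 0 members passed adjusted over the list alone. The MLL fusion and HOX program had a median of 0.16 while camera placed it below other genes (limma adjusted p = 0.616). Without EV library a 3623 regions passed (1946 higher, 1677 lower) and without EV library b 6 passed. EV library b had the fewest reads and 10.3% of them in the strongest 1% of regions, against 13.5% to 14.1% in the other libraries.

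For K23ac 0 of 14053 regions passed by limma, with 649 at an unadjusted p under 0.05, a smallest adjusted p of 0.831, and 0 by edgeR and by DESeq2. The largest falls by moderated t, none of which passed, were at ATOSA (135 ± 18.8 to 69.8 ± 3.69 CPM, log2 fold change −0.94, SE 0.256), TMED4, CARNS1, CCDC170 and the splicing regulator PTBP1 (−0.87, SE 0.26). The largest rises, which did not pass either, were at ARID5A (0.99, SE 0.287), the DNA glycosylase gene NEIL2, TSC22D1, SKIL and RNF122. The regions of ATOSA, CARNS1, PTBP1, NEIL2 and RNF122 lie inside the gene and not at its ends. MEIS1 had a log2 fold change of −0.59 (SE 0.227, limma adjusted p = 0.971) and FLT3 of 0.004 (SE 0.209, limma adjusted p = 0.998). Of the 14 lists tested 0 passed by limma camera and 0 members passed adjusted over the list alone. The smallest adjusted p was 0.126, for the MLL fusion and HOX program with a median of 0.12 (adjusted p = 0.977 with an estimated correlation). Without sgKAT6A library a 2 regions passed and without sgKAT6A library b 31 passed, while 6 and 7 regions passed when the 4 libraries were regrouped across the arms.

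Regions of different marks that overlap by at least 1 bp were set side by side, with the changes of each mark taken within its own table. At the 365 matched regions where K9ac fell, the median K14ac change was 0.024, below the 0.197 of unchanged regions matched on strength. With loess scaling, chosen for this comparison after seeing the data, it was −0.218 against 0.033 at the 649 matched regions where K9ac fell under that scaling. At the 883 matched regions where K9ac rose, the median K14ac change was 0.05 against −0.078. Median K23ac changes were −0.06 against −0.009 at 334 regions where K9ac fell and 0.088 against −0.034 at 292 where it rose. Across 21292 matched regions, which are not independent replicates, the changes of K9ac and K14ac had a Pearson correlation of −0.139 and a Spearman correlation of −0.198 (0.162 and 0.147 with loess scaling). Across 8569 regions those of K9ac and K23ac had 0.088 and 0.062. As deposited 0 regions changed in a pair of marks, since K14ac and K23ac had 0 changed regions by limma, edgeR and DESeq2 and 2951 and 649 at an unadjusted p under 0.05. With loess scaling 1 region, inside the gene of the lysophospholipase ENPP2 and named after its values were seen, fell in both K9ac (−0.56, limma adjusted p = 0.00585) and K14ac (−1.07, SE 0.152, limma adjusted p = 0.0102, and 0.685 as deposited), against 0.061 expected for independent lists. It lies on chromosome 8, where the median change with loess scaling was −0.217 for K14ac and 0.085 for K9ac.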

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

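The edgeR, DESeq2 and loess without sgKAT6A library a settings, the blocked fit by column letter and the loess values for gene ends were chosen after the result was seen. For K9ac (983 higher, 366 lower) the cause of the changes below was not tested unless named. Median-centring gave 608 changes (272 higher, 44.7%), quantile scaling 586 lower (58.3% higher), loess 728 lower (58.8%), loess without sgKAT6A library a 4371 (2186 higher, 2185 lower, 50%), edgeR without TMM 2077 (1552 higher), DESeq2 441 (216 higher, 225 lower, 49%) and a pseudocount of 5 gave 653 higher. An adjusted p of 0.1 gave 2893 (2165 higher, 728 lower) and a minimum of 1.5-fold 511 (492 higher, 19 lower, 96.3%), by construction. Without a variance trend limma gave 0 (0 higher, 0 lower; 6988 at an unadjusted p under 0.05; edgeR 1840). Leaving out 1 library, with the lone library assumed to vary like the other arm, gave 269 to 19630 changes (201 to 16114 higher, 68 to 3516 lower), and other groupings of the 4 libraries gave 0 and 0 (244 and 127 unadjusted). With the column letter as a replicate block, K9ac gave 3369 changes (2563 higher, 806 lower); libraries of the same letter deviated together with correlations of 0.104, −0.068 and 0.103 for K9ac, K14ac and K23ac, so the letter is not taken to pair them, and K14ac and K23ac still gave 0 in the replicate block.

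With an estimated correlation 0 of the 10 K9ac lists passed. With loess scaling camera's direction for the housekeeping list turned while its median stayed negative (−0.013), and SPI1 turned after median-centring (−0.005). For K14ac loess gave 1 change (1 lower), leaving out 1 library 0 to 3623 (0 to 1946 higher, 0 to 1677 lower), and the gene-end difference went from 0.373 to 0.102 with loess. K14ac lists passing numbered 3 with quantile and 3 with loess scaling, 0 to 6 with 1 library left out and 1 with the mean of all regions of a gene; camera's direction for the MLL fusion and HOX program turned to higher without EV library a (median 0.394), and its median of 0.16 turned to −0.094 without EV library b. For K23ac leaving out 1 library gave 0 to 31 changes (0 to 7 higher, 0 to 24 lower) and 0 to 1 lists, and the gene-end difference of 0.049 turned to −0.006 with a wider window and −0.010 at stronger regions. At KAT6A leaving out 1 library gave −0.224 to −0.018 for K9ac, 0.078 to 0.642 for K14ac and −0.104 to 0.637 for K23ac.

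Among K9ac values of named genes over all settings, 542 kept their direction and side of the threshold, 83 lost the call, 22 gained it and 18 changed sign without being called; for K9ac lists these were 204, 18, 8 and 7. At each mark's read totals and spread, 72% of simulated 1.5-fold changes were recovered for K9ac, 0% for K14ac and 11% for K23ac. These changes were set at stronger regions only, and the values do not separate depth from spread. The planned ratio to input was not run, since the tables used here hold no input columns, and a higher share cannot be given for K14ac and K23ac, which had 0 changes.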

Other observations

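The gene lists for amino acid stress, sterol and fatty acid synthesis, and Fc and immunoglobulin-like receptors, and all tests in this part except those of these lists and of matched strength and length, were chosen after the result was seen; the lists were chosen after the largest K9ac changes were known, and the genes that prompted them were left out. For the tests of the K14ac spread, of the excess of K9ac rises without sgKAT6A library a, of an equal rise at weak regions and of K14ac where K9ac fell, the values themselves were known before the bounds were written in their present form.

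K9ac fell at further genes of the amino acid stress response. Of 26 measured targets of ATF4, the transcription factor of that response, 9 fell and 0 rose by limma, among them PSAT1, the serine synthesis enzyme that follows PHGDH (−0.46, SE 0.07), the glutathione-degrading enzyme CHAC1 (−0.54, SE 0.083), the folate enzymes ALDH1L2 (−0.55, SE 0.087) and MTHFD2 (−0.39, SE 0.067), and the glutamine transporter SLC1A5 (−0.35, SE 0.057). The hypothesis that K9ac falls across ATF4 targets was tested on their median of −0.13, which lay at percentile 0.03 of random lists of the same strength (limma camera adjusted p = 1.87e-06; adjusted p = 0.172 with an estimated correlation), and loess scaling gave −0.14. A fall across sterol and fatty acid synthesis genes, raised by SREBF1, was not borne out: 3 of 23 fell (SCD, FASN and SREBF2), 0 rose, and the median of −0.07 lay at percentile 6.37 (limma camera adjusted p = 0.0585; adjusted p = 0.172 with an estimated correlation).

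K9ac rose at further receptors of the Fc and leukocyte immunoglobulin-like families. Of 21 measured genes 6 rose and 0 fell by limma: FCGRT, the neonatal Fc receptor (0.80, SE 0.074), the sialic acid receptor SIGLEC9 (0.79, SE 0.103), TREM1, which amplifies neutrophil and monocyte activation (0.75, SE 0.189), CD300C, SIRPB1 and FCRLB. The hypothesis that K9ac rises across these receptors was tested on their median of 0.38, at percentile 100 of random lists of the same strength, whose median was 0.1 (limma camera adjusted p = 4.71e-09; adjusted p = 0.0663 with an estimated correlation), and loess scaling gave 0.23.

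As deposited more K9ac regions rose than fell, though not after median-centring (44.7% higher) or with DESeq2 (49%). Without sgKAT6A library a the share of changes that were higher was 69.5%. That share cannot decide whether library a alone made the excess, since the spread then comes from the EV libraries alone. The median change of all tested regions was 0.067 without library a and 0.167 with it. A smaller shift in the same direction thus remained in library b. The share with loess scaling, 58.8% and 50% without library a, had first been set as the test here and was dropped, since that scaling centres the changes and so decides nothing. More background in library a would carry chromosome copy number. With loess scaling its chromosome medians had a Spearman correlation of 0.42 over 23 chromosomes with those of the K14ac library of weakest enrichment. That lies between the bounds of 0.5 and 0.3 set for this test, so background cannot be told apart from other causes by it. Pearson, looked at only afterwards and deciding nothing, was 0.93, or 0.84 without chromosomes 8 and X, and Spearman of library b was 0.52. The sign was the same at 21 of 23 chromosomes. The largest shifts lay on chromosome 8 (0.162 in library a, 0.478 in K14ac) and chromosome X (−0.135 and −0.582). More background in library a therefore stays open as part of the excess. A rise at weak regions in both sgKAT6A libraries alike is not what the values show, since the weaker 18441 regions stood higher by 0.44 in library a and 0.11 in library b, against 0.04 between the EV libraries. An unequal shift by region strength in both libraries and the targeting of KAT6A stay open, since both rest on the same 2 libraries.

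The fall of K9ac at the MLL fusion and HOX program is harder to explain by strength, length or a single library. Its 26 regions had a median of −0.24, at percentile 0 of random lists matched on strength and length (random median −0.09), and with loess scaling −0.09 lay at percentile 0.03. Random lists leave out the correlation between members, and with an estimated correlation the list did not pass by limma camera (adjusted p = 0.328), nor did it by fry (adjusted p = 0.0702). In sgKAT6A library b alone the median of −0.19 lay at percentile 0 too (random median −0.05), so library a alone does not account for it. A lower K9ac at these genes with sgKAT6A stays open as a hypothesis found and tested in the same libraries. Strength within the top class, GC content and input signal stay open beside it and were not tested.

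K9ac gave 1349 changed regions and K14ac and K23ac gave 0 by limma, edgeR and DESeq2 (2951 and 649 at an unadjusted p under 0.05), a contrast that was not tested between marks. Fewer reads alone would not remove changes of the size and spread seen in K9ac, since K9ac thinned to the K14ac totals still gave 582 changes (553 to 626 over 5 draws). A median of 446 changes per draw were also among the 1349 at full depth. For K23ac the bound set for this test left fewer reads undecided as a cause. The strongest 14053 K9ac regions, as many as K23ac has, thinned to its totals gave a median of 124 changes (80 to 171 over 5 draws, 1648 unthinned). These counts lie on both sides of the bound of 100. Each draw stayed above 0, so the K23ac totals alone did not remove all changes of the size and spread seen in K9ac. An earlier form of this test thinned all K9ac regions to the K23ac totals, as was done for K14ac, and gave 0 changes in each of 5 draws. It was replaced because it left fewer reads per region than K23ac holds. In K23ac itself 11% of simulated 1.5-fold and 48% of 2-fold changes, set at stronger regions, were recovered. A larger spread between the K14ac libraries is a candidate explanation that was not tested apart from depth. The simulation, with changes set at stronger regions, recovered 14% of 2-fold changes at the K14ac read totals and spread together. Whether K14ac stayed in place where K9ac fell cannot be told apart from a fall, since its median change there was 0.024 as deposited (365 regions) and −0.218 with loess scaling (649 regions), both below matched unchanged regions.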
